A study of Mus musculus with 24 samples.

How the data were processed

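RNA sequencing of mouse embryonic stem (ES) cells of 6 genotypes was re-analysed. The genotypes were wild type (WT), a knockout of Smchd1 (Smchd1 KO), a knockout of Dux (Dux KO), a knockout of both (Double KO), a triple knockout of Tet1, Tet2 and Tet3 (Tet TKO) and a knockout of the 3 Tet genes and Smchd1 (quad KO). There were 3 biological replicates per genotype. Each WT and Smchd1 KO replicate had been sequenced in 2 technical runs, which gave 24 libraries. Per the labels, reads were trimmed with Trim Galore, aligned with STAR 2.5.1 to the mouse genome build mm9 and handled with limma 3.38.2. The read counter, the gene annotation release and any filters were not stated.

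The deposited values are a normalized signal per gene, in CPM (counts per 1e6 counts) by their name. They come in 2 tables of 37310 gene entries each. One holds WT, Smchd1 KO, Dux KO and Double KO, and the other holds Tet TKO and quad KO. Whole reads could be recovered from the deposited signal: in every library, 100% of the values under 200 reads lay within 0.1 read of a whole multiple of the smallest step of that library. Column totals ran from 906871 to 1054029, so the values were CPM of an effective library size, and each table had been scaled on its own. The second table also holds 3 columns of per-sample values under the WT name that belong to no sample of the series, and these were not used. The design's comparisons of Tet TKO with WT and of quad KO with Smchd1 KO, and the difference of the Smchd1 effect between the Tet TKO and WT backgrounds, would each have crossed tables normalized separately. They were not analysed here, and levels set side by side across the tables were not tested.

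Depth, as gene reads per library in units of 1e6, was 17.0 to 74.4 in WT, 11.4 to 52.9 in Smchd1 KO, 13.2 to 15.6 in Dux KO, 14.8 to 17.2 in Double KO, 28.5 to 34.6 in Tet TKO and 27.3 to 29.1 in quad KO. The 10 most abundant genes took 4.42% to 9.16% of the reads of a library. Beside a group with no reads for a gene, the limit given is 3 reads over the whole group, and such a fold is a lower bound. These limits cover counting error only.

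The replicate names of Smchd1 KO did not say which 2 columns were runs of 1 replicate, so the 6 columns were joined into 3 pairs from their values together with the stated design. The noise ratio, which is the median over genes of the squared difference between 2 libraries in units of counting error, divided by the median that counting alone gives, was 1.32 to 1.62 within the pairs and 2.97 to 10.2 between them. It was 1.53 to 1.80 between the runs of a WT replicate, 1.31 to 2.04 between WT replicates and 1.42 to 1.62 between Tet TKO replicates. WT and Tet TKO replicates thus differed about as little as technical runs of 1 sample, although the design calls them biological replicates. The ratio reached 23.7 in Dux KO, 23.6 in Double KO and 9.14 in quad KO. The median standard deviation (SD) of a gene on the log2 scale was 0.05 in WT, 0.12 in Smchd1 KO, 0.30 in Dux KO, 0.31 in Double KO, 0.06 in Tet TKO and 0.13 in quad KO.

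Technical runs were averaged and counted once. Genes with at least 0.5 CPM in at least 3 biological samples of a table were kept, which left 16200 genes in the first table and 14920 in the second. Log2(CPM + 0.5) was fitted in R 4.3.3 with limma 3.58.1, with 1 mean per genotype, all genotypes of a table in a single fit and an intensity trend in the moderated test. Comparisons were Smchd1 KO vs WT, Dux KO vs WT, Double KO vs Dux KO, Double KO vs Smchd1 KO, quad KO vs Tet TKO, and the difference between the Smchd1 effect in Dux KO and that in WT (the interaction). All tests are two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes come from this scale, and the added 0.5 makes them smaller than ratios of CPM for genes with few reads. Errors beside CPM values are SD with n = 3 throughout.

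Lists of genes were fixed before the data were examined: 2-cell-stage genes, other DUX targets, pluripotency factors, the 3 protocadherin clusters, imprinted genes, Hox genes, germline genes, the X-linked Rhox, Xlr and Magea families, DNA methylation factors, markers of endoderm, mesoderm, ectoderm, trophoblast and fibroblasts, p53 targets, interferon genes, histone genes whose RNA lacks a poly(A) tail, and mitochondrial and abundant noncoding RNA. The targeted genes were left out of each. Dnmt3l, Trim28 and Xlr genes, among others, sit in more than 1 list. None of the 22 protocadherin beta genes in the tables passed the filter. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. Where no count adjusted over the list alone is given, it equals that over all genes. List calls in this text are those at the preset correlation. Of them, only that of the X-linked families in quad KO vs Tet TKO held with an estimated correlation. All its measured members but Rhox6 and Rhox9 passed the filter only through Tet TKO. Their fall follows from the filter, so this call is not independent of it.

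Named genes were chosen by a rule fixed before the data were examined. It takes the targeted genes, the 5 largest rises and 5 largest falls among genes that passed with a mean CPM of at least 1 and no overlap between the replicates of the 2 groups (a split that chance gives to 10% of unchanged genes), and 2 members of each list with the smallest adjusted p. It takes 4 members for the 2-cell-stage, pluripotency and imprinted lists, and the most abundant member where none passes. For the interaction it takes only targeted, 2-cell-stage and protocadherin genes. Zfp951 and X-linked genes named beyond this rule, and the sums without Zfp951, were chosen after their values were seen.

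Gene identifiers were matched by Ensembl ID to GENCODE M21, in which 87.4% were found. Because the alignments are to mm9 and that annotation is to GRCm38, no coordinates are given, and chromosomes were used only to group genes. The share of a transcript's 50-base words that also occur in another gene was counted for the 2-cell-stage list and the X-linked families. Median deviations per chromosome from WT or Tet TKO were taken over genes with a mean CPM of at least 2.

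The alternatives chosen in advance were pseudocounts of 0.1 and 2, no filter, a filter of 2 CPM, median-ratio scaling, quantile normalization, array quality weights, a fit to the compared genotypes alone, the replicate number as a block, each technical run alone, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, each replicate left out in turn, and an estimated correlation for the lists. Others were added after seeing the data: chromosomes with a shifted median left out, chromosome medians centred, the 4 samples with a strong chromosome shift left out (which leaves 1 replicate of Dux KO and 2 each of Smchd1 KO and Double KO), and reads thinned to 13.2 (in units of 1e6) per biological sample in the first table and 27.3 in the second. No scaling moved the median log2 change of all genes by more than 0.1.

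Tests on simulated data used the real depths, each gene's mean over its table and 1 spread per genotype. Changed genes, 200 per comparison, had a mean CPM of at least 2. These simulations cover no genes near 0 reads in a genotype or with their own spread, so real recovery may be lower. In these, limma recovered 90% of 2-fold changes in Smchd1 KO vs WT, 82% in Dux KO vs WT, 79% in Double KO vs Dux KO, 81% in Double KO vs Smchd1 KO, 36% in the interaction and 100% in quad KO vs Tet TKO, and all 4-fold changes. False calls made up 0%, 1.09%, 40.9% (of 303, against 2 in the real data), 9.50%, 0.730% and 0.498% of calls in that order. The pooled spread was thus too large where replicates were tight and too small for Dux KO and Double KO.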

Results

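Gene expression was measured by RNA sequencing in mouse embryonic stem (ES) cells of 6 genotypes with 3 biological replicates each, in 24 libraries. SMCHD1 is a chromatin protein of the SMC family with roles in silencing on the X chromosome and at imprinted and clustered genes. DUX is a homeobox transcription factor that switches on genes of the 2-cell embryo, and the TET enzymes oxidise 5-methylcytosine. Gene reads per library, in units of 1e6, ran from 11.4 to 74.4 in the table of WT, Smchd1 KO, Dux KO and Double KO, and from 27.3 to 34.6 in the table of Tet TKO and quad KO. These tables were normalized separately, so levels given side by side across them were not tested. Replicates of WT and of Tet TKO differed about as little as technical runs of 1 sample (noise ratio 1.31 to 2.04 and 1.42 to 1.62, against 1.53 to 1.80 between WT runs), which limits what their spread says about separate cultures. Values in CPM carry the SD over 3 replicates, and tests were made with limma unless another tool is named.

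Transcript levels of the targeted genes were checked first. Smchd1 (ENSMUSG00000024054.5) stood at 206 ± 2.28 CPM in WT and 193 ± 19.6 CPM in Dux KO, against 60.4 ± 15.3 CPM in Smchd1 KO and 79.0 ± 8.48 CPM in Double KO. It fell 3.46-fold in Smchd1 KO vs WT (adjusted p = 0.000395) and 2.43-fold in Double KO vs Dux KO (adjusted p = 0.0294). In the other table it fell 7.31-fold, from 155 ± 5.46 CPM in Tet TKO to 23.4 ± 14.7 CPM in quad KO (adjusted p = 0.000827). Tet1 had 2244 ± 39.4 CPM in WT, 272 ± 3.21 CPM in Tet TKO and 289 ± 7.22 CPM in quad KO. Tet2 had 432 ± 9.71, 337 ± 6.57 and 235 ± 2.81 CPM in the same genotypes, and Tet3 had 54.2 ± 0.430, 44.4 ± 1.47 and 45.3 ± 1.58 CPM, so transcripts of both were still present. Tet2 fell 1.43-fold in quad KO vs Tet TKO (adjusted p = 7.57e-05).

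The Dux transcript gave only a weak check of the Dux knockout. The gene named Dux in the tables (ENSMUSG00000058537.2) is named AW822073 in the reference annotation, where the name Duxf3 belongs to the gene the tables call Gm10807 (ENSMUSG00000075046.3). Dux had 0.0983 ± 0.0517 CPM in WT, 0.697 ± 0.248 CPM in Smchd1 KO, 0.149 ± 0.258 CPM in Dux KO, 0.0815 ± 0.141 CPM in Double KO, 0.357 ± 0.143 CPM in Tet TKO and 0.477 ± 0.218 CPM in quad KO. Dux KO replicate 1 alone held 0.447 CPM, and the other 2 had no reads. Gm10807 had 0.0884 ± 0.0512, 0.405 ± 0.281, 0.0497 ± 0.0861, 0.122 ± 0.106, 0.335 ± 0.137 and 0.141 ± 0.165 CPM in the same order. Duxbl had a mean of at most 0.300 CPM in every genotype. All 3 were under the filter and were not tested.

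Smchd1 KO was compared with WT for the effect of losing Smchd1. Of 55 2-cell-stage entries, 33 passed the filter. A530040E14Rik, Sp110, Tdpoz4, B020004J07Rik, Gm13078, Gm13109, Dub2a, Arg2, Gm4027, Abcb5 and Spz1 had means under 0.5 CPM in WT, Dux KO and Double KO. These were kept mainly through Smchd1 KO, so the filter favoured a rise for them. Genes of the 2-cell embryo rose together: 31 of the 33 measured members rose, none fell and 2 did not pass, and 31 rose adjusted over the list alone. Their median log2 change was 2.03 (1.28 with a pseudocount of 2). The summed level of all 33 was 42.0 ± 1.14 CPM in WT and 220.3 ± 75.9 CPM in Smchd1 KO, and that of the 32 other than Zfp951, a zinc finger gene set aside after its values were seen, was 40.6 ± 1.22 and 213 ± 71.3 CPM. Among the largest rises, Usp17l5 of the Usp17 deubiquitinase family went from 0.934 ± 0.0890 to 8.82 ± 2.76 CPM (6.29-fold on the fitted scale, adjusted p = 0.000395), Gm5662 from 2.24 ± 0.306 to 20.6 ± 7.71 CPM (7.31-fold, adjusted p = 0.000568) and Gm8300 from 1.97 ± 0.362 to 15.1 ± 5.82 CPM (6.05-fold, adjusted p = 0.00106). Zscan4f, a zinc finger gene expressed at the 2-cell stage, rose 4.81-fold, BB287469 (ENSMUSG00000071217.2) rose 6.15-fold, and Gm8994, from the list of other DUX targets, rose 6.44-fold. Camera placed the list above other genes (adjusted p = 1.46e-57 at the preset correlation, adjusted p = 0.0952 with an estimated correlation). Some members share most of their 50-base words with another gene, among them Zscan4f (86.8%), Zscan4c (85.5%), Gm5662 (81.3%) and Gm2016 (77.9%). The share was 44.7% for Usp17l5 and 26.6% for Gm8300, and it could not be counted for BB287469 (ENSMUSG00000071217.2). The level of a single copy is thus uncertain. Among the 12 members with under 20% of their 50-base words in another gene, 10 rose, with a median of 1.61.

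Counting these, 105 genes were higher and 39 lower in Smchd1 KO. Of the 144 in all, 107 changed at least 2-fold. The largest falls on the fitted scale apart from Smchd1 itself were Tril, a Toll-like receptor accessory protein (4.19-fold, adjusted p = 0.00978), the erythroid spectrin gene Spna1 (3.91-fold, adjusted p = 0.00211), the ciliary neurotrophic factor receptor Cntfr (3.07-fold, adjusted p = 0.0151) and Ankrd34a (2.90-fold, adjusted p = 0.0101). Of 20 p53 targets, 2 rose, the death receptor gene Eda2r (1.67-fold) and the BH3-only gene Pmaip1 (1.89-fold). Adjusted over the list alone 8 rose, and the median was 0.49 (adjusted p = 5.04e-05, adjusted p = 0.433 with an estimated correlation). Germline genes had positive changes in 31 of 34 members. Their median was 0.52, with none past the test over all genes and 6 higher adjusted over the list alone (adjusted p = 6.62e-06, adjusted p = 0.518 with an estimated correlation). Fibroblast markers had a median of 0.49 with none of 15 passing (2 adjusted over the list alone; adjusted p = 0.0352, adjusted p = 0.518 with an estimated correlation). The most abundant member, Fn1, was at 822 ± 15.8 CPM in WT and 759 ± 80.5 CPM in Smchd1 KO. Hnf4a, a transcription factor of visceral endoderm, rose 2.76-fold as the only passing member of 20 endoderm markers (median 0.54, list adjusted p = 0.0513).

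Lower medians were found for pluripotency factors (-0.24, none of 28 passing, 3 lower adjusted over the list alone; adjusted p = 0.0319, adjusted p = 0.544 with an estimated correlation) and DNA methylation factors (-0.21, none of 15 passing; adjusted p = 0.0295, adjusted p = 0.433 with an estimated correlation). Trim28, a corepressor in both lists, was at 1398 ± 41.9 CPM in WT and 1049 ± 135 CPM in Smchd1 KO. Histone genes without a poly(A) tail had a median of -0.18, and 2 of 63 fell, Hist2h4 by 2.28-fold and Hist2h2ac by 2.41-fold (adjusted p = 0.000566, adjusted p = 0.631 with an estimated correlation). Hoxa3 fell 2.45-fold, alone among 19 Hox genes. Chromosome 6, which holds the Hoxa cluster, was at -0.50 in Smchd1 KO replicate 2, and with chromosome medians centred Hoxa3 was at -1.13 on the log2 scale and lost its call (adjusted p = 0.0590), as did Eda2r (0.69, adjusted p = 0.0562). Adjusted over the list alone 2 Hox genes were higher and 7 lower (list adjusted p = 0.0786). No list call was made for other DUX targets (median 0.21, 1 of 15 rose, 3 adjusted over the list alone, adjusted p = 0.0786), mesoderm (-0.16, 0.241), trophoblast (0.13, 0.671), interferon genes (0.23, 0.445), abundant noncoding RNA (-0.05, 0.467) or the X-linked families (0.15, 0.467), each given as median and adjusted p. Quantile normalization gave the trophoblast and X-linked medians the opposite sign. Imprinted genes had a median of 0.04, a mean of -0.06 and a downward test (adjusted p = 0.829). Ectoderm genes had a median of -0.03, a mean of 0.10 and an upward test (adjusted p = 0.848). Pcdha11, the measured alpha protocadherin, stood at 0.427 ± 0.0962 CPM in WT and 1.28 ± 0.106 CPM in Smchd1 KO (adjusted p = 0.143, list adjusted p = 0.0786, 1 higher adjusted over the list alone). Pcdhgc5 of the gamma cluster changed by -0.16 on the log2 scale (list adjusted p = 0.509).

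The count of 144 genes was 230 with edgeR, 1082 with DESeq2, 71 with a filter of 2 CPM, 9292 with array quality weights, 6852 in a fit to WT and Smchd1 KO alone. It was 2751 without the 4 samples with a strong chromosome shift, which left 2 replicates of Smchd1 KO and 1 of Dux KO in the fit. The share of higher genes was 72.9% as reported, 49.9% with array quality weights, 48.6% in the fit to 2 genotypes and 42.7% without those samples. Leaving out WT replicate 1, 2 or 3 gave 51, 55 or 56 genes and leaving out Smchd1 KO replicate 1, 2 or 3 gave 58, 72 or 79. Tril, Cntfr, Ankrd34a, Eda2r, Pmaip1, Hist2h4, Hist2h2ac, Hoxa3 and Hnf4a each lost their call without at least 1 of these replicates, while the 6 named risers of the 2-cell-stage and DUX lists kept theirs. List calls were lost without Smchd1 KO replicate 2 for DNA methylation factors (adjusted p = 0.0717) and fibroblast markers (0.185), and without Smchd1 KO replicate 3 for pluripotency factors (0.0866). These 3 calls also ended with quantile normalization (0.156, 0.0570 and 0.234), with a filter of 2 CPM (0.0646, 0.0746 and 0.0746) and without chromosomes 1, 6 and 8 (0.0548, 0.112 and 0.0590). Those of DNA methylation factors and fibroblast markers ended with array quality weights (0.0520 and 0.133) and in the fit to 2 genotypes (0.0849 and 0.0875). Without a filter the fibroblast median was 0.20 (adjusted p = 0.348), and it ran from 0.21 with a pseudocount of 2 to 0.92 with edgeR.

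**Figure D1:**
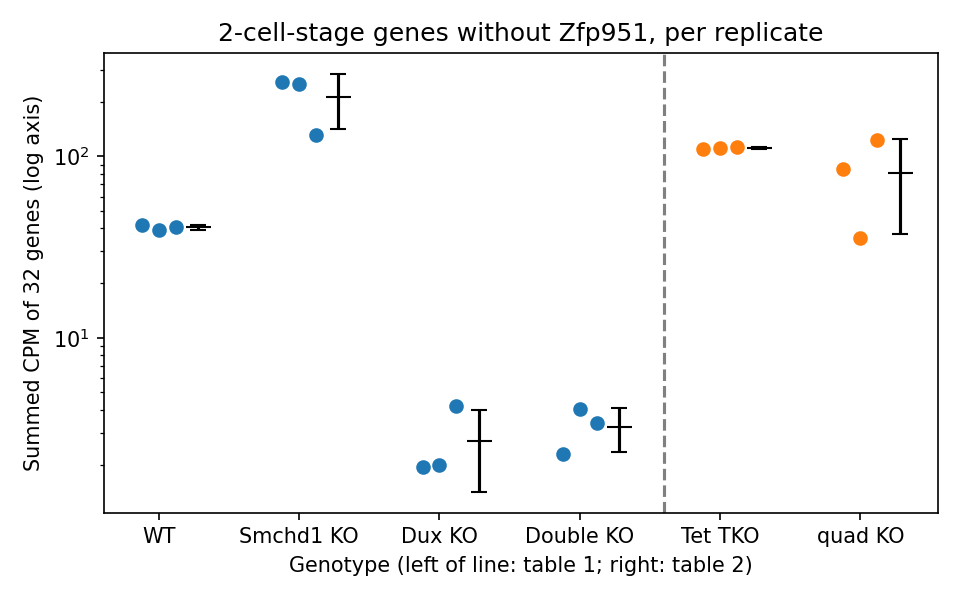
Summed CPM of the 32 genes of the 2-cell-stage list other than Zfp951 on a log axis, 1 point per replicate (blue, first table; orange, second table), with the mean and SD of 3 replicates as a bar beside them. The Smchd1 KO replicates lie between 130.4 and 257 CPM and the WT replicates between 39.3 and 41.7 CPM, while no replicate of Dux KO or Double KO exceeds 4.20 CPM. Zfp951 was set aside after its values were seen. With it, Double KO replicate 3 is at 38.9 CPM and the WT replicates are at 40.7 to 42.9 CPM. The dashed line separates tables that were normalized separately.

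Dux KO was compared with WT for the effect of losing Dux alone. Genes of the 2-cell embryo fell from their already low WT level: 18 of 33 fell, none rose and 15 did not pass, with 24 lower adjusted over the list alone. In Dux KO, 23 members had no reads in any replicate. The median log2 change was -1.16 as fitted and -2.45 with those members at the limit of 3 reads over the group. Its size followed the added constant: it was -2.83 with a pseudocount of 0.1, -0.39 with one of 2 (8 fell), -0.65 without a filter, -6.86 with edgeR and -5.42 with DESeq2 (27 fell). Zscan4d was at least 48.2-fold lower (3.35 ± 0.264 CPM in WT, no reads in Dux KO), Gm8994 at least 36.7-fold and Zscan4c at least 31.6-fold. Gm5662 and Gm8300 fell to 0.0249 ± 0.0431 and 0.0477 ± 0.0415 CPM (adjusted p = 0.00555 and 0.00586). Usp26, an X-linked ubiquitin protease gene of the list, fell 6.13-fold to 2.14 ± 1.73 CPM (adjusted p = 0.00917). The list lay below other genes (adjusted p = 8.40e-20, adjusted p = 0.471 with an estimated correlation). Without WT replicate 1, 2 or 3, the members that fell numbered 1, 7 and 1.

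In all, 264 genes were higher and 380 lower in Dux KO. Of these 644, 194 changed at least 2-fold. The imprinted growth-regulating RNA H19 had the largest fall on the fitted scale, although the CPM bounds above are larger for Zscan4d, Gm8994 and Zscan4c. It went from 26.6 ± 1.15 to 1.65 ± 0.833 CPM (13.2-fold, adjusted p = 0.00598). Phlda2 (2.48-fold) and Gab1 (1.43-fold) fell while Zim1 rose (2.09-fold) among 50 imprinted genes (median -0.10, list adjusted p = 0.851, 1 higher and 3 lower adjusted over the list alone). Gpa33, a cell surface antigen of gut epithelium, rose 4.80-fold (adjusted p = 0.0104), Dusp27 4.43-fold, the collagen gene Col20a1 3.91-fold, the tubulin polyglutamylase gene Ttll6 3.70-fold and Gm13014 3.59-fold. The de novo DNA methyltransferase gene Dnmt3a fell from 371 ± 3.75 to 152 ± 29.6 CPM (adjusted p = 0.00655), alone among 15 DNA methylation factors (median -0.19, 2 lower adjusted over the list alone, list adjusted p = 0.0904). The pluripotency marker Utf1 fell 1.68-fold, alone of 28 (median -0.22, 2 adjusted over the list alone, list adjusted p = 0.184).

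Of 20 p53 targets, 4 rose, among them the p53 ubiquitin ligase Mdm2 (1.62-fold) and Perp (1.40-fold), with 4 higher and 1 lower adjusted over the list alone and a median of 0.27 (adjusted p = 0.00317, adjusted p = 0.567 with an estimated correlation). Without Dux KO replicate 3 that median was 0.11 (adjusted p = 0.184), without Dux KO replicate 1 it was 0.49 (adjusted p = 2.43e-06), and without the samples with a strong chromosome shift, on 1 Dux KO sample assumed to vary like the other groups, it was -0.05 (adjusted p = 0.989). Histone genes without a poly(A) tail had a median of -0.62: 5 of 63 fell, with Hist1h4a (1.93-fold) and Hist1h4c (1.77-fold) the clearest, and 31 adjusted over the list alone (adjusted p = 2.07e-12, adjusted p = 0.567 with an estimated correlation). Abundant noncoding RNA had a median of 0.43, with none of 20 passing and 4 adjusted over the list alone (adjusted p = 0.000199, adjusted p = 0.234 with an estimated correlation). Its member mt-Co1 was at 7366 ± 242 CPM in WT and 9274 ± 919.9 CPM in Dux KO. Hoxa3 (2.36-fold) and Hoxa5 (2.07-fold) were among 4 of 19 Hox genes that fell (7 adjusted over the list alone; adjusted p = 0.0111, adjusted p = 0.471 with an estimated correlation). The Hoxa cluster lies on chromosome 6, whose median was lower in Dux KO replicates 2 (-0.44) and 1 (-0.18). With chromosome medians centred Hoxa5 (log2 change -0.85, adjusted p = 0.104) and Gab1 (-0.33, adjusted p = 0.122) lost their calls. Without chromosomes 1, 6 and 8 the Hox median was -0.03 (adjusted p = 0.967), and without Dux KO replicate 1 it was -0.35 (adjusted p = 0.106). The Hox call also ended with a filter of 2 CPM (0.232), array quality weights (0.182) and chromosome medians centred (0.0681).

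The interferon gene Ifit2 fell 1.74-fold, alone of 10 (median 0.19, list adjusted p = 0.851). Among other DUX targets Gm8994 fell, alone of 15 (median -0.23, list adjusted p = 0.246). No member passed over all genes among germline genes (median -0.15, adjusted p = 0.851), the X-linked families (0.11, 0.851), mesoderm (-0.33, 0.410), ectoderm (-0.36, 0.529; 1 lower adjusted over the list alone) and trophoblast (-0.23, 0.992). None passed either among fibroblast markers (median -0.14, mean -0.25, upward test, adjusted p = 0.992) or endoderm markers (median 3.76e-05, mean -0.01, upward test, adjusted p = 0.851). The most abundant members were Lama1 for endoderm (290.1 ± 8.75 CPM in WT, 429 ± 242 CPM in Dux KO) and Fn1 for fibroblasts (822 ± 15.8 and 1079 ± 137 CPM). Pcdha11 changed by 0.18 (list adjusted p = 0.851) and Pcdhgc5 by -0.03 on the log2 scale (list adjusted p = 0.992; 0.08 with quantile normalization).

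The number of calls changed strongly with the libraries in the fit, which also set the pooled spread. Leaving out WT replicate 1, 2 or 3 left 2, 16 or 2 genes, leaving out Dux KO replicate 2 left 95 and leaving out Dux KO replicate 3 gave 2790. Of the 24 named genes that passed, 22 lost their call without at least 1 replicate, Gm8994 and Zscan4d being the exceptions. The count was 32 with the replicate number as a block, 338 without a filter, 344 with quantile normalization, and 368 with technical run 2 alone. It was 2606 with DESeq2, 6431 with array quality weights and 5479 without the 4 samples with a strong chromosome shift, which left 1 Dux KO sample, assumed to vary like the other groups. The share of higher genes was 41.0% as reported, 51.4% with median-ratio scaling, 58.1% with DESeq2 and 62.0% with edgeR.

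Double KO was compared with Dux KO for the effect of losing Smchd1 in cells with a Dux knockout. Only 2 genes passed: Smchd1 fell from 193 ± 19.6 to 79.0 ± 8.48 CPM, and Wnk3-ps rose from 38.6 ± 7.80 to 116 ± 9.50 CPM (log2 change 1.58, adjusted p = 0.00719). Most 2-cell-stage genes stayed near 0 reads. None of 33 passed. Their summed level was 11.05 ± 6.29 CPM in Dux KO and 17.9 ± 18.3 CPM in Double KO, with Double KO replicate 3 at 38.9 CPM against 40.7 to 42.9 CPM in WT. Without Zfp951, set aside after its values were seen, the sums were 2.71 ± 1.29 and 3.24 ± 0.883 CPM. The median log2 change was 0.03 (adjusted p = 0.285). It was -0.03 with quantile normalization, 0.0867 with a pseudocount of 0.1 (adjusted p = 0.0224), 0.38 with edgeR (adjusted p = 0.0119) and 0.40 with DESeq2 (adjusted p = 0.0778), so the list passed upward in 2 of these fits. In both genotypes 26 of the 33 members had at most 3 reads over the group. For these, a proportional rise of the size seen in Smchd1 KO could not have been detected gene by gene at this depth. Zfp951 was at 8.34 ± 7.47 CPM in Dux KO and 14.6 ± 18.3 CPM in Double KO, and at 35.5 CPM in Double KO replicate 3.

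Several lists of lineage genes had higher medians in Double KO, with no member past the test over all genes. The medians were 0.76 for fibroblast markers (6 of 15 higher adjusted over the list alone; adjusted p = 9.49e-07, adjusted p = 0.125 with an estimated correlation) and 0.70 for trophoblast (6 of 17; adjusted p = 9.49e-07, adjusted p = 0.194 with an estimated correlation). For ectoderm the median was 0.43 (1 of 12; adjusted p = 0.00310, adjusted p = 0.125 with an estimated correlation). The trophectoderm keratin Krt18 was at 46.6 ± 61.4 CPM in Dux KO and 181 ± 178 CPM in Double KO. Hox genes were positive in 18 of 19 (median 0.30, 4 adjusted over the list alone; adjusted p = 7.47e-06, adjusted p = 0.125 with an estimated correlation). Without chromosomes 1, 6 and 8 the Hox list gave adjusted p = 0.195. Imprinted genes had a median of 0.22 (2 of 50 adjusted over the list alone; adjusted p = 0.00438, adjusted p = 0.125 with an estimated correlation). Their most abundant member, Peg10, was at 696 ± 584 and 2224 ± 2272 CPM. Pluripotency factors had a median of -0.17 (1 lower adjusted over the list alone; adjusted p = 0.0190, adjusted p = 0.591 with an estimated correlation). Abundant noncoding RNA had a median of -0.23 (adjusted p = 0.00324, adjusted p = 0.125 with an estimated correlation), with Malat1 at 10031 ± 1746 and 9578 ± 3716 CPM.

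No list call was made in Double KO vs Dux KO for other DUX targets (median 0.03, mean -0.10, downward test, adjusted p = 0.518) or p53 targets (median 0.02, mean -0.02, downward test, adjusted p = 0.972). The same held, as median and adjusted p, for germline genes (-0.04, 0.849), the X-linked families (0.15, 0.518), DNA methylation factors (0.00, 0.374; 1 higher adjusted over the list alone), endoderm (-0.47, 0.232), mesoderm (0.13, 0.189), interferon genes (-0.05, 0.518; 1 lower adjusted over the list alone) and histone genes (0.02, 0.476). Pcdha11 was at 0.563 ± 0.241 CPM in Dux KO and 1.44 ± 0.875 CPM in Double KO (adjusted p = 0.350, list adjusted p = 0.0755, 1 adjusted over the list alone). Pcdhgc5 changed by 0.12 (list adjusted p = 0.518).

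The count of 2 came with 1583 genes at an unadjusted p under 0.05, and edgeR also called 2 genes while DESeq2 called 220. It was 12 without a filter, 1 with array quality weights, 0 in a fit to Dux KO and Double KO alone and 3364 without the samples with a strong chromosome shift, which set 1 Dux KO sample against 2 of Double KO and took its spread from the other groups. It was 1, 0 and 129 without Dux KO replicate 1, 2 and 3 and 0, 146 and 83 without Double KO replicate 1, 2 and 3. List calls were lost for pluripotency without Dux KO replicate 1 (median -0.0479, adjusted p = 0.590) or Double KO replicate 1 or 2 (medians -0.00412 and -0.0990, adjusted p = 0.149 and 0.409), and for imprinted genes without Double KO replicate 1 (median 0.0698, adjusted p = 0.129). They were also lost for ectoderm without Dux KO replicate 3 (median 0.0782, adjusted p = 0.0503) or Double KO replicate 3 (median 0.34, adjusted p = 0.0612), and for noncoding RNA without Double KO replicate 2 or 3 (0.0507, 0.0612). Without Dux KO replicate 3 the trophoblast median was 1.15, that of imprinted genes 0.10 and that of pluripotency -0.29, and without Double KO replicate 3 the last was -0.36. Without the samples with a strong shift, on 1 Dux KO sample, trophoblast and fibroblast medians were both 1.35. Array quality weights ended the calls of pluripotency, ectoderm (median 0.17) and noncoding RNA (0.0559, 0.0804 and 0.0674).

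Double KO was compared with Smchd1 KO for the effect of losing Dux in cells with a Smchd1 knockout. Of 33 2-cell-stage genes, 32 fell, both over all genes and adjusted over the list alone, and only Zfp951 did not pass. For the members kept mainly through Smchd1 KO, the filter favoured a fall. The median log2 change was -3.24 as fitted and -4.05 with the 13 members without reads in Double KO at the limit of 3 reads over the group. It was -5.26 with a pseudocount of 0.1, -1.68 with one of 2, -7.85 with edgeR and -7.38 with DESeq2. Usp17l5 was at least 145-fold lower (8.82 ± 2.76 CPM in Smchd1 KO, no reads in Double KO). Gm5662 fell from 20.6 ± 7.71 to 0.0818 ± 0.0933 CPM, Zscan4d from 16.7 ± 6.62 to 0.0396 ± 0.0686 CPM, Zscan4c from 14.5 ± 5.85 to 0.0402 ± 0.0348 CPM, Gm8300 from 15.1 ± 5.82 to 0.0600 ± 0.0594 CPM and the DUX target Gm8994 35.2-fold to 0.0606 ± 0.0612 CPM. Their adjusted p lay between 6.84e-07 and 1.34e-06. Camera gave adjusted p = 5.22e-56 for the list, and adjusted p = 0.103 with an estimated correlation. Of 15 other DUX targets 2 fell, Gm8994 and the elongation factor gene Whsc2, also called Nelfa (1.52-fold). Adjusted over the list alone 4 fell (median -0.39; adjusted p = 0.00397, adjusted p = 0.490 with an estimated correlation).

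In all, 226 genes were higher and 483 lower in Double KO than in Smchd1 KO, and 296 of the 709 changed at least 2-fold. The largest rises were the ubiquitin ligase gene Mid1 (4.72-fold, adjusted p = 0.00428), the semaphorin Sema3e (4.11-fold, adjusted p = 0.00343), the primitive streak signal Wnt3 (3.69-fold), endothelin gene Edn1 (3.61-fold) and Ehd2 (3.48-fold). Germline genes fell in 8 of 34 cases (11 adjusted over the list alone), led by the piRNA pathway gene Asz1 (2.39-fold) and the testis tubulin Tuba3b (4.37-fold). Their median was -0.65 (adjusted p = 4.38e-05, adjusted p = 0.573 with an estimated correlation). Endoderm markers were lower in all 20 cases by sign, and Hnf4a alone passed (log2 change -1.32). Their median was -0.79 (adjusted p = 0.0187, adjusted p = 0.578 with an estimated correlation), and the call was lost with edgeR (median -0.42, adjusted p = 0.115), DESeq2 (-0.43, 0.182) and array quality weights (-0.40, 0.238). Trophoblast markers had a median of 0.76: the growth factor receptor Fgfr2 rose 2.60-fold, 4 of 17 adjusted over the list alone (adjusted p = 0.00334, adjusted p = 0.573 with an estimated correlation). Fibroblast markers Col3a1 (0.654 ± 0.463 to 3.31 ± 1.00 CPM) and Fn1 (1.56-fold) rose beside these, with 3 higher and 2 lower adjusted over the list alone (median 0.50, list adjusted p = 0.0854). Fn1 lies on chromosome 1, raised by 0.53 in Double KO replicate 3, and with chromosome medians centred its log2 change went from 0.64 to 0.48 and its call was lost (adjusted p = 0.0800).

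Among pluripotency factors Fgf4 (2.03-fold) and Tdgf1 (1.98-fold) fell, 2 of 28, 3 adjusted over the list alone (median -0.12, list adjusted p = 0.251). Hox genes rose in 3 of 19 cases, Hoxa7 (2.54-fold) and Hoxa3 (1.98-fold) among them (median 0.31, list adjusted p = 0.0707, 5 higher and 1 lower adjusted over the list alone). Chromosome 6, which holds the Hoxa cluster, had a lower median in Smchd1 KO replicate 2 (-0.50) and Double KO replicate 3 (-0.49). The neural genes Nes rose (2.41-fold) and Sox3 fell (2.23-fold; list median 0.34, adjusted p = 0.349, 2 higher and 2 lower adjusted over the list alone). The gene of the SMCHD1 partner LRIF1, named 4933421E11Rik in the tables, rose 1.88-fold, alone of 15 DNA methylation factors and partners (2 adjusted over the list alone; median -0.02, upward test, adjusted p = 0.705; the median was 0.01 with either other scaling). Ascl2, a placental transcription factor, fell 2.06-fold as the only passing imprinted gene of 50 (none adjusted over the list alone, median 0.18, list adjusted p = 0.0867). Perp rose 1.51-fold among p53 targets (median -0.12, list adjusted p = 0.559, 2 higher and 4 lower adjusted over the list alone). Histone genes Hist2h3c1 (3.66-fold) and Hist2h3c2 (3.02-fold) fell, 2 of 63 (median -0.38; adjusted p = 0.00297, adjusted p = 0.683 with an estimated correlation). Abundant noncoding RNA had a median of 0.28 (2 of 20 adjusted over the list alone; adjusted p = 0.0237, adjusted p = 0.490 with an estimated correlation). This call ended without a filter (median 0.0117, adjusted p = 0.355), with technical run 2 alone (0.0752, adjusted p = 0.109) and with quantile normalization (0.23, adjusted p = 0.0589).

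No list call was made between these genotypes for mesoderm, in which Wnt3 alone rose (median 0.23, adjusted p = 0.384), for interferon genes (median -0.22, adjusted p = 0.493, 2 lower adjusted over the list alone) or for the X-linked families (median 0.18, mean -0.03, upward test, adjusted p = 0.860). Pcdha11 changed by 0.03 and Pcdhgc5 by 0.24 on the log2 scale (list adjusted p = 0.860 and 0.384). The count of genes was 99, 166 and 135 without Smchd1 KO replicate 1, 2 and 3, and 191, 1386 and 2428 without Double KO replicate 1, 2 and 3. Of the 29 named genes that passed, 19 lost their call without at least 1 replicate. The count was 121 in a fit to the 2 genotypes alone, 2456 with DESeq2, 2673 with array quality weights and 5806 without the samples with a strong chromosome shift, which left 2 replicates of each genotype. The share of higher genes, 31.9% as reported, was 48.2% with edgeR and 50.8% with DESeq2. Leaving out Double KO replicate 2 ended the list calls of DUX targets, endoderm, histones and noncoding RNA (adjusted p = 0.0511, 0.220, 0.220 and 0.0602) and replicate 1 those of trophoblast and histones (medians 0.40 and -0.13, adjusted p = 0.0581 and 0.242). The endoderm call also ended without Double KO replicate 3 (median -0.21, adjusted p = 0.347) or Smchd1 KO replicate 3 (median -0.28, adjusted p = 0.342), while the median was -1.47 without Double KO replicate 1 (adjusted p = 3.32e-09) and -1.24 without Smchd1 KO replicate 2 (adjusted p = 0.000746), and the noncoding RNA call without Smchd1 KO replicate 2 (0.153).

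The interaction asked whether the Smchd1 effect differed between the Dux KO and WT backgrounds. It was lower in Dux KO for 24 of 33 2-cell-stage genes (31 adjusted over the list alone) and higher for none. The median difference was -1.94 on the log2 scale. For the members kept mainly through Smchd1 KO, the filter favoured such a difference. Usp17l5 differed by -2.65 (adjusted p = 0.0181), Gm5662 by -2.73 (0.0224), Zscan4f by -2.16 (0.0224) and Gm8300 by -2.57 (0.0236). Camera gave adjusted p = 1.53e-36 for the list and adjusted p = 0.305 with an estimated correlation. This difference is one of log2(CPM + 0.5), and with most members near 0 reads in Dux KO it depends on the added 0.5. The median was -1.20 with a pseudocount of 2, and 1 member passed with one of 0.1. EdgeR called none of the members and gave the list an adjusted p of 0.847, with Zscan4f at 1.15. DESeq2 called none and gave adjusted p = 0.000748. Without WT replicate 1, 2 or 3 or Dux KO replicate 2 no member passed, without Smchd1 KO replicate 1 or 2 only 1 did, and without Double KO replicate 1 only 3. In all, 25 genes had a higher and 58 a lower Smchd1 effect in Dux KO.

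Hox genes had a more positive Smchd1 effect in Dux KO in 4 of 19 cases (9 higher and 1 lower adjusted over the list alone; median 0.56, adjusted p = 0.00218, adjusted p = 0.371 with an estimated correlation). Without chromosomes 1, 6 and 8 the Hox median was -0.26 (adjusted p = 0.739). Trophoblast markers had a median difference of 0.55 (adjusted p = 0.0111, adjusted p = 0.524 with an estimated correlation) and histone genes one of 0.22 (1 of 63 higher, 2 adjusted over the list alone; adjusted p = 0.00459, adjusted p = 0.633 with an estimated correlation). DNA methylation factors had 0.10 (1 of 15 higher, 3 adjusted over the list alone; adjusted p = 0.0459, adjusted p = 0.371 with an estimated correlation; -0.04 with quantile normalization). Negative differences were found for germline genes (-0.66, 1 of 34 adjusted over the list alone; adjusted p = 0.00228, adjusted p = 0.524 with an estimated correlation), endoderm (-0.73, 1 of 20 lower; adjusted p = 0.0349, adjusted p = 0.552 with an estimated correlation) and p53 targets (-0.45, 1 of 20 lower; adjusted p = 0.00459, adjusted p = 0.524 with an estimated correlation; 0.00605 and adjusted p = 0.796 without the samples with a strong chromosome shift, on 1 Dux KO sample). No list call was made for other DUX targets (-0.32, 1 of 15 lower, 2 adjusted over the list alone, adjusted p = 0.0756), imprinted genes (0.25, 1 higher adjusted over the list alone, 0.0756), mesoderm (0.60, 0.0756), ectoderm (0.39, 1 of 12 higher, 0.101), fibroblast markers (0.43, 1 higher adjusted over the list alone, 0.129), interferon genes (-0.18, 1 lower adjusted over the list alone, 0.365), the X-linked families (-0.23, 0.892) or noncoding RNA (-0.37, 0.293). Pluripotency factors had a median of -0.08, a mean of 0.04 and an upward test (adjusted p = 0.871), with 1 lower adjusted over the list alone. Pcdha11 and Pcdhgc5 differed by -0.14 and 0.27 (list adjusted p = 0.871 and 0.395).

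The interaction count of 83 fell to 0 without any 1 of the WT replicates or without Dux KO replicate 2, to 4 or 5 without Smchd1 KO replicate 1 or 2 and to 19 without Double KO replicate 1. It rose to 673 and 175 without Dux KO replicate 1 and 3 and to 1203 and 154 without Double KO replicate 2 and 3. It was 7 with edgeR, 946 with DESeq2, 9 with a pseudocount of 0.1, 11 with a filter of 2 CPM, and 48 with technical run 2 alone. It was 21 with reads thinned to one depth, 2242 with array quality weights and 1688 without the samples with a strong chromosome shift, a fit with 1 Dux KO sample, assumed to vary like the other groups. The share of genes with a more positive effect in Dux KO, 30.1% as reported, was 52.9% with array quality weights. Without Dux KO replicate 1 the calls of Hox, trophoblast, histone and endoderm genes ended (adjusted p = 0.0522, 0.203, 0.263 and 0.114), the histone median turning to -0.04. Those of histones (median -0.08, adjusted p = 0.841) and endoderm (median -0.16, adjusted p = 0.228) ended without Double KO replicate 3, that of p53 targets without Dux KO replicate 3 (median -0.18, adjusted p = 0.0641), and that of trophoblast without Double KO replicate 1 (median 0.24, adjusted p = 0.0997). The endoderm call ended also without Smchd1 KO replicate 3 (median -0.31, adjusted p = 0.301), Dux KO replicate 3 (median -0.36, adjusted p = 0.255) or Double KO replicate 2 (adjusted p = 0.262), while its median was -1.74 without Double KO replicate 1 (adjusted p = 1.78e-07), -1.22 without Smchd1 KO replicate 2 and -1.20 without Dux KO replicate 2. The germline median was -0.37 without Double KO replicate 1 and -0.40 without Dux KO replicate 2 (adjusted p = 0.0190 and 0.0497), and without Dux KO replicate 3 the trophoblast and histone medians were 1.09 and 0.47. That of endoderm ended with edgeR (0.140), DESeq2 (0.142), array quality weights (median 0.10, adjusted p = 0.758) and without chromosomes 1, 6 and 8 (0.0758). A filter of 2 CPM ended the calls of Hox (0.108), trophoblast (0.0589) and DNA methylation genes (0.0755). The call for DNA methylation factors ended without WT replicate 1, Smchd1 KO replicate 2, Dux KO replicate 1 or 2, or Double KO replicate 1 or 2, with adjusted p from 0.0513 to 0.114, and with edgeR (0.105).

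**Figure D2:**
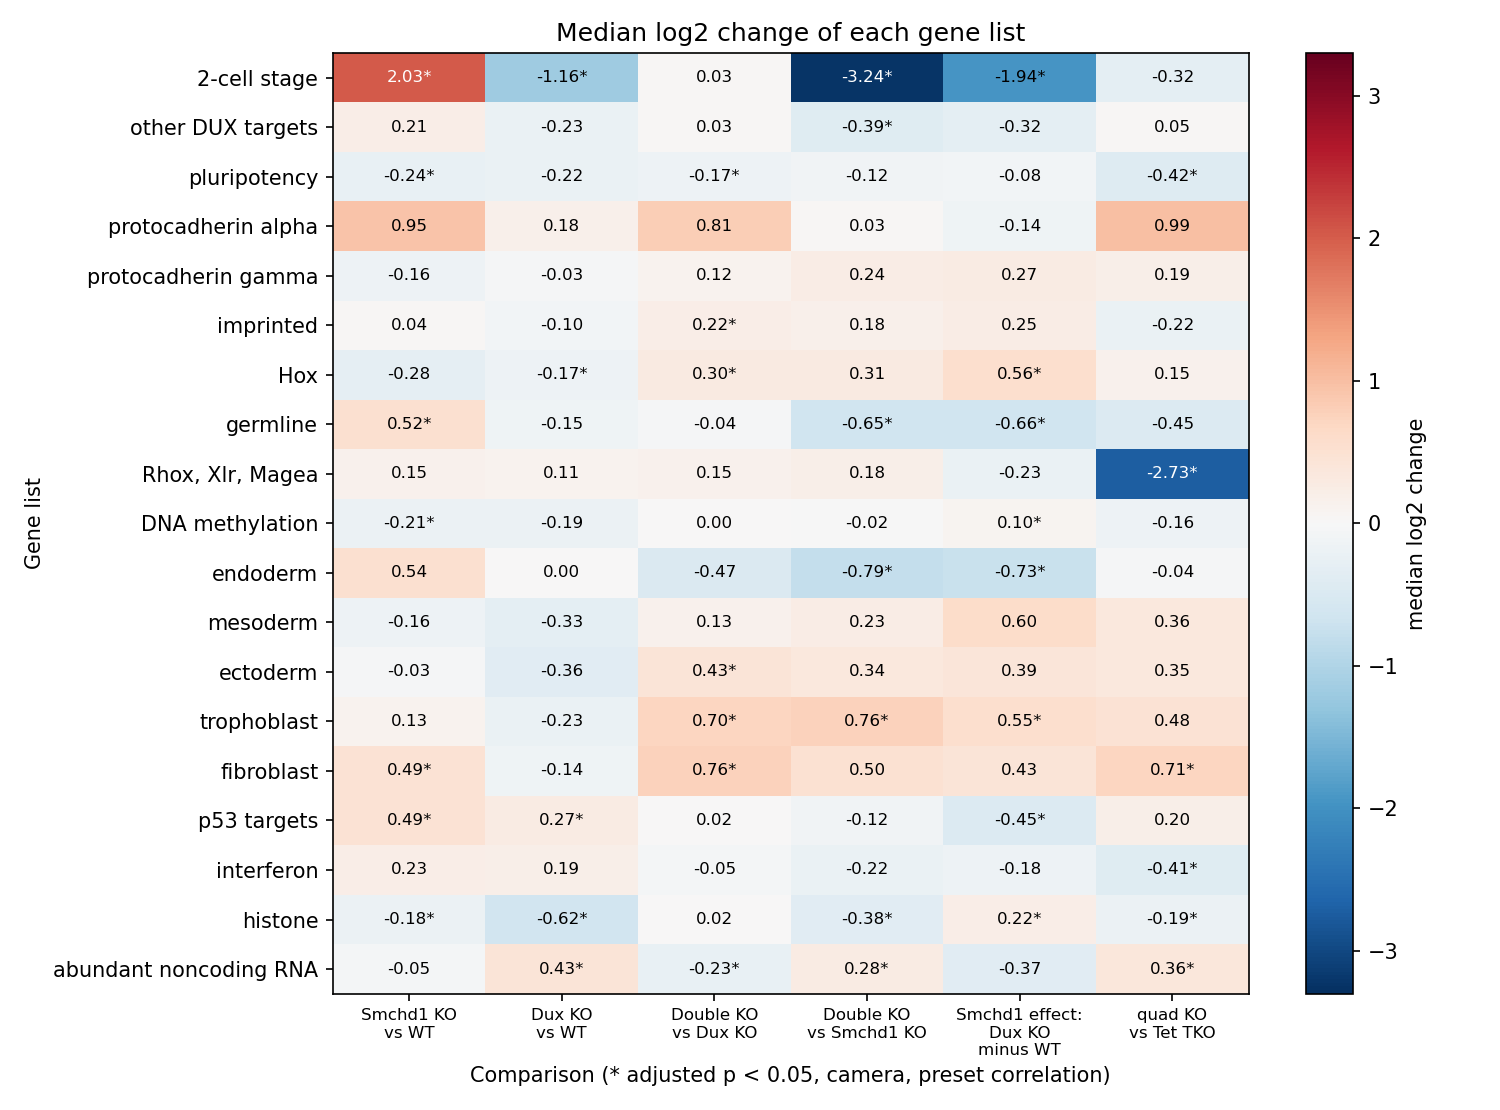
Median log2 change of the measured members of each gene list (vertical axis) in each comparison (horizontal axis), printed in each cell and coloured from blue (lower) to red (higher), with a star for an adjusted p under 0.05 in camera at the preset correlation. The 2-cell-stage list stands at 2.03 in Smchd1 KO vs WT and 0.03 in Double KO vs Dux KO. The Rhox, Xlr and Magea families stand at -2.73 in quad KO vs Tet TKO, the only star that held with an estimated correlation. This star is not independent of the filter, which forces the fall of all measured members but Rhox6 and Rhox9.

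Quad KO was compared with Tet TKO for the effect of losing Smchd1 in cells with a knockout of the 3 Tet genes. Of 58 entries of the X-linked Rhox homeobox, Xlr and Magea families, 15 passed the filter. Apart from Rhox6 and Rhox9, these were under 0.5 CPM in every quad KO replicate and passed only through Tet TKO. For them a lower level without overlap between the genotypes follows from the filter. All 15 measured members fell, over all genes and adjusted over the list alone, each with no overlap between the replicates. Their median log2 change was -2.73 (adjusted p = 7.08e-14, and adjusted p = 0.0299 with an estimated correlation). The median was -4.17 with a pseudocount of 0.1, -1.30 with one of 2, -6.60 with edgeR, -6.63 with DESeq2 and -0.28 without a filter. Xlr3a (ENSMUSG00000057836.6) fell from 18.5 ± 0.802 to 0.183 ± 0.136 CPM (28.2-fold on the fitted scale, adjusted p = 3.94e-06) and Xlr3c from 7.53 ± 0.676 to 0.324 ± 0.0405 CPM (adjusted p = 7.67e-06). Xlr copies share sequence (44.8% of the 50-base words of Xlr3a and 72.1% of those of Xlr3c occur in another gene), so the level of a single copy is uncertain. The 5 members with under 20% of their 50-base words in another gene, Rhox1, Rhox6, Rhox9, Rhox13 and Magea4, all fell, with a median of -1.60. The median of all measured genes on the X chromosome was also lower in quad KO, by -0.24, -0.23 and -0.23 in the 3 replicates.

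**Figure D3:**
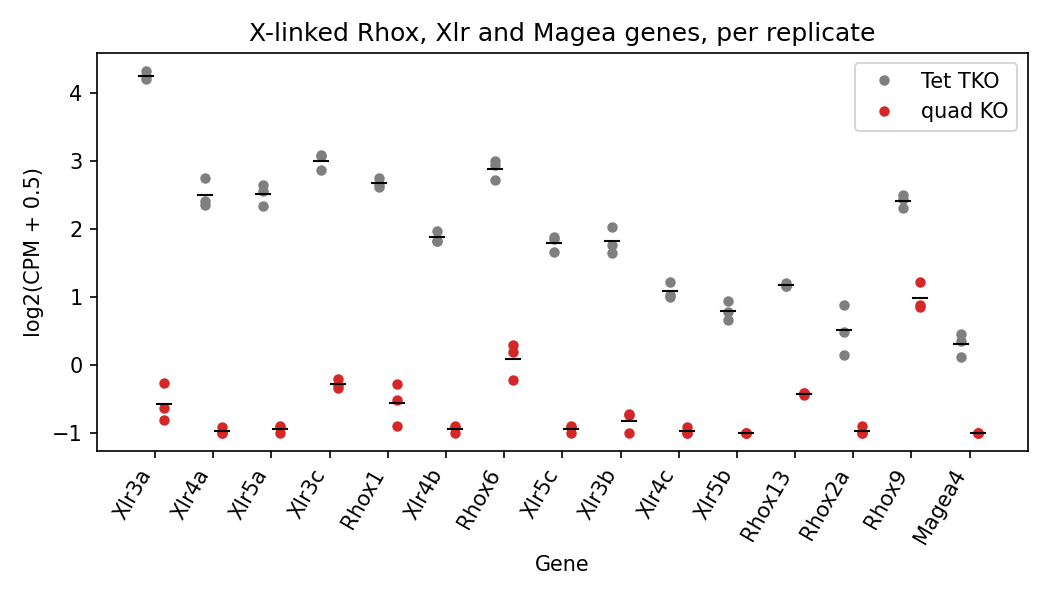
Log2(CPM + 0.5) of the 15 measured Rhox, Xlr and Magea genes (horizontal axis), with 1 point per replicate of Tet TKO (grey) and quad KO (red) and a bar at the mean of 3 replicates. Every quad KO point lies below every Tet TKO point of the same gene, an order that the filter forces apart from Rhox6 and Rhox9. The change runs from -4.82 for Xlr3a to -1.30 for Magea4.

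Across all genes, 2546 were higher and 3073 lower in quad KO, 5619 of the 14920 tested, and 671 of them changed at least 2-fold. The share of higher genes was 45.3% as reported, 52.8% with quantile normalization (3131 higher, 2799 lower) and 52.9% without the chromosomes with a shifted median (2334 higher, 2074 lower). Pramel6 and Pramel7, leucine-rich repeat genes of the early embryo, fell from 9.01 ± 0.255 to 0.0469 ± 0.0216 CPM and from 9.83 ± 0.325 to 0.195 ± 0.174 CPM (adjusted p = 2.67e-06 and 2.08e-05). Aard fell from 25.8 ± 0.982 to 1.32 ± 0.997 CPM (adjusted p = 0.000309). Rises of the same rank were those of the myelin gene Mal (3.90-fold), Fndc3c1 (3.69-fold), the axonal kinesin Kif1a (3.31-fold), the mitochondrial ribosomal RNA mt-Rnr1 (4.08-fold) and mmu-mir-689-2 (4.30-fold). Among pluripotency factors 17 of 28 fell and 3 rose (17 and 4 adjusted over the list alone). Tbx3 fell 4.84-fold (adjusted p = 2.67e-06), Klf4 3.35-fold, Gdf3 1.76-fold and Fgf4 1.68-fold. The list median was -0.42 (adjusted p = 0.000206, adjusted p = 0.0918 with an estimated correlation).

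Fibroblast markers moved the other way, with 11 of 15 higher and none lower (13 adjusted over the list alone). The smooth muscle gene Tagln rose from 10.2 ± 0.102 to 26.3 ± 1.96 CPM, the fibronectin gene Fn1 from 377 ± 11.8 to 533 ± 37.7 CPM. The list median was 0.71 (adjusted p = 4.50e-06, adjusted p = 0.0548 with an estimated correlation). Lineage markers split: trophoblast genes rose in 10 and fell in 4 of 18 cases, with Cdx2 up 2.96-fold and Dlx3 1.84-fold (list adjusted p = 0.132). Ectoderm genes rose in 9 and fell in 5 of 17 cases, with Zic1 up 2.93-fold and Nes 1.70-fold (0.0650). Mesoderm genes rose in 5 and fell in 2 of 13 cases, with Mixl1 up 1.66-fold and Cdx1 down 1.70-fold (0.237). In the endoderm list the laminin Lama1 (3.74-fold) and Hnf4a (3.24-fold) were among 5 of 19 that fell, and 4 rose (0.456). Adjusted over the list alone, 11 trophoblast, 11 ectoderm, 5 mesoderm and 4 endoderm genes were higher and 5, 5, 3 and 6 lower. In that order the medians were 0.48, 0.35, 0.36 and -0.04.

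Imprinted genes changed in both directions, 11 higher and 23 lower of 49 (12 and 23 adjusted over the list alone; median -0.22, list adjusted p = 0.132). H19 fell from 272 ± 9.53 to 47.9 ± 72.0 CPM, the zinc finger gene Plagl1 fell 2.58-fold, the X-linked Xlr3b and Xlr4b fell 6.19-fold and 7.01-fold, and the growth factor adapter Grb10 rose 1.79-fold. The call of H19 (adjusted p = 0.0277) was lost with edgeR, with DESeq2, and without quad KO replicate 1 or any Tet TKO replicate (adjusted p up to 0.152). Germline genes also split, 10 higher and 15 lower of 33, with the germ cell helicase Ddx4 up 1.67-fold and Tuba3a down 2.72-fold (10 and 16 adjusted over the list alone; median -0.45, list adjusted p = 0.237). Of 15 DNA methylation factors 7 fell, among them the methyltransferase cofactor Dnmt3l (1.87-fold) and Uhrf1 (1.34-fold), and 2 rose (8 and 3 adjusted over the list alone; median -0.16, list adjusted p = 0.0825). Hoxd13 rose 1.69-fold and Hoxa10 fell 2.82-fold, within 4 Hox genes higher and 1 lower of 18, with the same counts adjusted over the list alone (median 0.15, list adjusted p = 0.237). Pcdha11 rose 1.98-fold (adjusted p = 0.00346, list adjusted p = 0.188) and Pcdhgc5 was higher only adjusted over the list alone, by 0.19 (list adjusted p = 0.315).

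Of 28 measured 2-cell-stage genes 5 had positive and 23 negative changes, and their estimated inter-gene correlation was 0.709. Zfp951 rose (1.65-fold), Usp26 fell 3.56-fold from 26.1 ± 1.02 CPM and Gm2016 fell from 0.995 ± 0.207 to 0.367 ± 0.230 CPM (Gm2016 not without Tet TKO replicate 1 or 3, adjusted p up to 0.0846). Adjusted over the list alone 1 was higher and 1 lower. The median was -0.32, and the list test did not pass (adjusted p = 0.293). The median was -0.64 without quad KO replicate 3 (adjusted p = 0.0119, 10 fell) and 0.15 without quad KO replicate 2 (adjusted p = 0.286). It was -0.15 with a pseudocount of 2, -0.0637 without a filter, -0.10 with array quality weights and -0.13 with edgeR and with DESeq2. The summed level of the 33 members measured in the first table, 5 of them not tested here, was 122 ± 2.48 CPM in Tet TKO and 98.9 ± 45.0 CPM in quad KO, and without Zfp951 it was 111 ± 1.63 CPM in Tet TKO and ranged from 35.2 to 123 CPM over the quad KO replicates. Among other DUX targets, D14Ertd668e fell from 27.7 ± 0.683 to 2.07 ± 0.239 CPM and Zfp600 rose 1.63-fold, 2 higher and 1 lower of 14 in all and adjusted over the list alone (median 0.05, mean -0.10, upward test, adjusted p = 0.314).

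Interferon genes fell in 6 of 11 cases, the antiviral genes Xaf1 (log2 change -1.72) and Oas1a (2.16-fold) first (2 higher and 7 lower adjusted over the list alone; median -0.41, adjusted p = 0.0326, adjusted p = 0.442 with an estimated correlation; adjusted p = 0.177 without a filter). Perp (1.65-fold) and Zmat3 (1.35-fold) were among 5 of 20 p53 targets that rose, and 1 fell, with the same counts adjusted over the list alone (median 0.20, list adjusted p = 0.0650). Histone genes without a poly(A) tail fell in 32 of 63 cases and rose in 1 (35 lower and 1 higher adjusted over the list alone), the linker histones Hist1h1c and Hist1h1b by 1.27-fold and 1.22-fold. The median was -0.19 (adjusted p = 2.81e-05, adjusted p = 0.475 with an estimated correlation). Mitochondrial and abundant noncoding RNA rose in 9 of 19 cases, over all genes and adjusted over the list alone, Malat1 by 1.63-fold and mt-Nd1 by 1.29-fold (median 0.36; adjusted p = 0.00118, adjusted p = 0.442 with an estimated correlation). The mt-Nd1 gene did not pass with quantile normalization (adjusted p = 0.382). The total of 5619 genes was 10792 with array quality weights and 3661, 3541 and 3712 without Tet TKO replicate 1, 2 and 3.

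**Figure D4:**
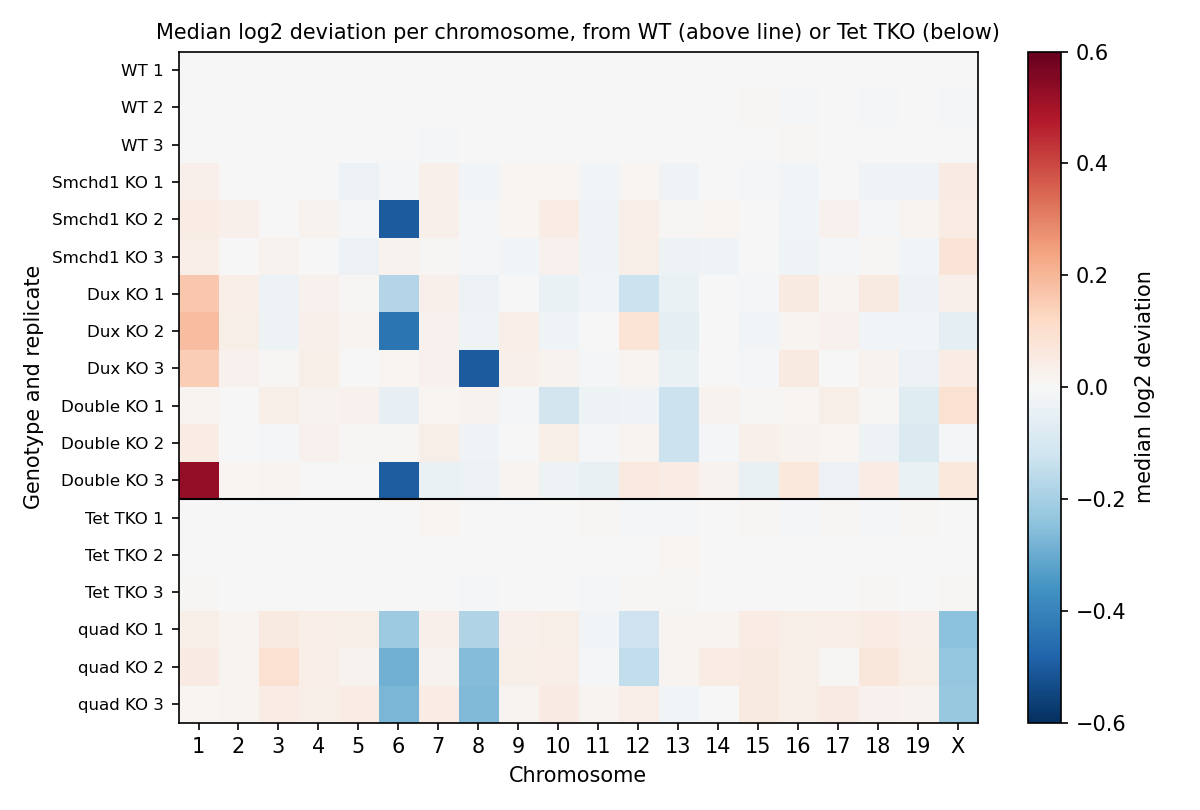
Median log2 deviation of the genes of each chromosome (horizontal axis) in each replicate (vertical axis) from the mean of WT (above the line) or Tet TKO (below it), coloured from blue (lower) to red (higher). Shifts beyond 0.4 stand in chromosome 6 of Smchd1 KO replicate 2, Dux KO replicate 2 and Double KO replicate 3, chromosome 8 of Dux KO replicate 3 and chromosome 1 of Double KO replicate 3.

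Medians of whole chromosomes were shifted, some in single replicates and some in all 3 of a genotype. On the log2 scale chromosome 6 was at -0.50 in Smchd1 KO replicate 2, -0.44 in Dux KO replicate 2 and -0.49 in Double KO replicate 3, chromosome 8 at -0.50 in Dux KO replicate 3 and chromosome 1 at 0.53 in Double KO replicate 3. In quad KO, chromosome 6 was at -0.22, -0.29 and -0.28 in replicates 1, 2 and 3, and chromosome 8 at -0.18, -0.26 and -0.27. In Dux KO chromosome 1 was at 0.16, 0.19 and 0.15 in the 3 replicates, and chromosome 6 at -0.18 in replicate 1. Each of these medians covers between 543 and 691 genes.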

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

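The tests of depth, of a proportional rise and of similar copies were chosen after the result was seen, and the count of other splits before. What drew attention here was a difference between groups. The Smchd1 effect differed between the Dux KO and WT backgrounds in 83 genes, and the median difference over the 2-cell-stage list was -1.94 on the log2 scale. Among its members Usp17l5 differed by -2.65, Gm5662 by -2.73, Zscan4f by -2.16 and Gm8300 by -2.57. All 5 values are differences of log2(CPM + 0.5), and edgeR called none of the members (list adjusted p = 0.847; 1.53e-36 with limma, 0.305 with an estimated correlation, and 0.000748 or lower under the other alternatives run). Zscan4f was at 1.15 with edgeR.

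The pattern is that 2-cell-stage genes were higher in Smchd1 KO than in WT and were not called higher in Double KO than in Dux KO in the reported fit, although the list was with edgeR (median 0.38, adjusted p = 0.0119) and with a pseudocount of 0.1 (0.0867, adjusted p = 0.0224). That the rise was seen in Smchd1 KO only through deeper libraries is argued against, since 27 of 32 members were higher than in WT with reads thinned to one depth, although the members that differed in the interaction went from 24 of 33 to 8 of 32. Sharing of reads between similar copies is argued against for the rise in Smchd1 KO. The 12 members with mostly unique sequence had a median log2 change of 1.61, although some of them passed the filter mainly through Smchd1 KO. A proportional rise too small to be seen cannot be told apart from no rise: over the 31 members under 0.5 CPM in Dux KO, the sum was 0.572 ± 0.444 CPM in Dux KO and 1.43 ± 0.708 CPM in Double KO, and the ratio of summed CPM between a Double KO and a Dux KO replicate ran from 0.899 to 33.5, on 1 to 12 reads in Dux KO and 13 to 37 in Double KO, against a lowest ratio of 3.82 between Smchd1 KO and WT. A rise to the absolute level of Smchd1 KO was absent, and a need for Dux in that rise may be a biological explanation that the design names but that stays a hypothesis.

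Of 100 ways drawn to regroup the samples for the interaction, 4 gave at least as many genes as the real 83, that one included. That share is under 0.05, but most of the other ways mix genotypes that differ, which widens the spread and holds their counts down. Since the count was also 0 without any 1 WT replicate or Dux KO replicate 2, a random grouping of the samples is not taken as excluded. The 3 other counts were 197, 515 and 3360, the highest many times the real one, which points to a structure of the samples other than genotype.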

How the results depend on the processing

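Leaving out shifted chromosomes, centring chromosome medians, leaving out samples with a strong shift and thinning reads were chosen after the data were seen. The estimated correlation for the 2-cell-stage list was in the design from the start, and for the other lists among the alternatives. Where no reason is given, the cause was not tested. Of the named genes that passed, 8 of 17 kept their call under every alternative in Smchd1 KO vs WT, 2 of 24 in Dux KO vs WT, 0 of 2 in Double KO vs Dux KO, 7 of 29 in Double KO vs Smchd1 KO, 0 of 4 in the interaction and 48 of 51 in quad KO vs Tet TKO. The only named gene that passed and took the opposite sign was Zscan4f in the interaction (1.15 with edgeR).

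The estimated correlation of the 2-cell-stage list was 0.711 in the first table, against the preset 0.01. The medians of this list kept their values in camera with it. They were 2.03 in Smchd1 KO vs WT (adjusted p = 0.0952) and -1.16 in Dux KO vs WT (0.471). In Double KO vs Smchd1 KO and the interaction they were -3.24 (0.103) and -1.94 (0.305), and all of these lost their calls. Adjusted p of other lists that lost theirs were, in Smchd1 KO vs WT, 0.544 (pluripotency), 0.518 (germline, fibroblast), 0.433 (DNA methylation, p53) and 0.631 (histone). In Dux KO vs WT they were 0.471 (Hox), 0.567 (p53, histone) and 0.234 (noncoding RNA), and in Double KO vs Dux KO 0.591 (pluripotency), 0.194 (trophoblast) and 0.125 (imprinted, Hox, ectoderm, fibroblast, noncoding RNA). In Double KO vs Smchd1 KO they were 0.490 (DUX targets, noncoding RNA), 0.573 (germline, trophoblast), 0.578 (endoderm) and 0.683 (histone). In the interaction they were 0.371 (Hox, DNA methylation), 0.524 (germline, trophoblast, p53), 0.552 (endoderm) and 0.633 (histone), and in quad KO vs Tet TKO 0.0918 (pluripotency), 0.0548 (fibroblast), 0.442 (interferon, noncoding RNA) and 0.475 (histone).

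The 2-cell-stage median in Double KO vs Dux KO was 0.0867 with a pseudocount of 0.1 (adjusted p = 0.0224), 0.38 with edgeR (0.0119), 0.40 with DESeq2 and -0.0342 with quantile normalization. The size of the other medians followed the added constant. Pseudocounts of 0.1 and 2 gave 2.55 and 1.28 in Smchd1 KO vs WT, -2.83 and -0.39 in Dux KO vs WT, -5.26 and -1.68 in Double KO vs Smchd1 KO and -2.28 and -1.20 in the interaction, where 1 and 20 members passed. EdgeR gave -6.86, -7.85 and -1.75 (0.847) in the last 3 and DESeq2 -5.42, -7.38 and -2.04. Without a filter Dux KO vs WT had -0.65. In quad KO vs Tet TKO the median was -0.0637 with no filter, -0.10 with array quality weights, and -0.13 with edgeR and with DESeq2.

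Some medians of lists that kept their calls moved by over 1.5 times as well. Those of Hox genes ran from -0.79 without the samples with a strong shift to -0.0657 with no filter in Dux KO vs WT and from 0.27 with a pseudocount of 2 to 1.30 with DESeq2 in the interaction. In Double KO vs Dux KO they ran from 0.11 with a pseudocount of 2 to 0.72 without the samples with a strong shift. Double KO vs Smchd1 KO had trophoblast at 1.30 and histones at -0.64 without Double KO replicate 3, and DUX targets at -0.61 with a pseudocount of 0.1 and -0.25 without Double KO replicate 1. Array quality weights gave 0.98 for trophoblast, 0.0836 for histones and 0.21 for DNA methylation factors in the interaction. The median of noncoding RNA with no filter was 0.24 in Dux KO vs WT and 0.15 in quad KO vs Tet TKO, where that of fibroblast markers was 0.42 with a pseudocount of 2 and that of the X-linked families ran from -6.63 with DESeq2 to -0.28 with no filter.

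Counts of genes are given in the order Smchd1 KO vs WT, Dux KO vs WT, Double KO vs Dux KO, Double KO vs Smchd1 KO, the interaction and quad KO vs Tet TKO, where they moved beyond 1.5 times. Array quality weights gave 9292, 6431, 1, 2673, 2242 and 10792. DESeq2 gave 1082, 2606, 220, 2456 and 946 in the first 5, and leaving out samples with a strong shift 2751, 5479, 3364, 5806 and 1688, with 1 Dux KO replicate and 2 each of Smchd1 KO and Double KO left and assumed to vary like the other groups. The compared genotypes alone gave 6852, 0 and 121 (Smchd1 KO vs WT, Double KO vs Dux KO, Double KO vs Smchd1 KO), where the spread is taken from fewer groups. The 0 stood beside 1583 genes at an unadjusted p under 0.05 in the fit to all genotypes with limma, and edgeR called 2. EdgeR gave 230 in Smchd1 KO vs WT and 7 in the interaction, a filter of 2 CPM 71 and 11 in the same comparisons, no filter 338 in Dux KO vs WT and 12 in Double KO vs Dux KO, and technical run 2 alone 368 in Dux KO vs WT and 48 in the interaction. Dux KO vs WT had 344 with quantile normalization and 32 with the replicate block, and the interaction 9 with a pseudocount of 0.1 and 21 with thinned reads.

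Leaving out 1 replicate gave 51 to 79, 2 to 2790, 0 to 146, 99 to 2428, 0 to 1203 and 3541 to 7638 genes in that order. The 2-cell-stage medians then ran from 1.84 to 2.38 in Smchd1 KO vs WT, -1.26 to -1.05 in Dux KO vs WT, 0 to 0.0810 in Double KO vs Dux KO, -3.55 to -3.04 in Double KO vs Smchd1 KO, -2.18 to -1.77 in the interaction and -0.64 to 0.15 in quad KO vs Tet TKO. These fits have fewer samples, and the remaining libraries of a genotype are assumed to vary like the others.

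The block was run though replicate numbers may not pair the samples. Deviations of same-numbered replicates from genotype means correlated at 0.03 to 0.17 (WT, Dux KO) and 0.06 to 0.23 (WT, Double KO). Values were -0.03 to 0.02 (Tet TKO, quad KO) and -0.13 to 0.47 (Dux KO, Double KO), against -0.37 to 0.20 for other numbers. The 0.47 was that of replicates 2. Their noise ratio was 5.29, against at least 12.8 between replicates within either genotype. The block was not run for comparisons with Smchd1 KO or the interaction, because those columns carry no replicate numbers. The compared genotypes alone equal the reported fit for the interaction and the second table, which has no technical runs either. No alternative was run for the 3 comparisons across tables. Depth limits the 2-cell-stage genes in Dux KO and Double KO, where 26 of 33 have at most 3 reads in both.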

Other observations

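The tests of chromosome shifts, of the X chromosome and of similar copies were chosen after the results were seen, and the counts of other splits before. Rhox, Xlr and Magea genes were lower in quad KO than in Tet TKO in 15 of 15 cases. All but Rhox6 and Rhox9 passed the filter only through Tet TKO, so their direction follows from it. A shift of the whole X chromosome is argued against as the whole cause, since the list median was -2.50 with chromosome medians centred. Sharing of reads between similar copies is argued against by the median of -1.60 over the 5 members with mostly unique sequence. No test separated the loss of Smchd1 from other differences between the lines, so an effect of that loss may be a biological explanation but stays a hypothesis.

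Medians of whole chromosomes were shifted beyond 0.4 in 4 samples of the first table. All 59 of 59 runs of 50 neighbouring genes on these chromosomes moved the same way, which a change in chromosome copy number in part or all of the cells predicts and which may be its result. A loss from 3 to 2 copies would give -0.58 on the log2 scale, beyond each of the lower medians. The raised chromosome 1 of Double KO replicate 3 was uneven, with runs from 0.0639 to 0.92, past the 0.58 of a gain from 2 to 3 copies. The median size of shift over chromosomes in these samples was at most 0.0412. This could not test scaling of the library, because each sample's median over genes was first set to 0, which removes such scaling. No biological explanation was tested.

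In each 2-group comparison the 6 samples make 10 splits, too few for a share under 0.05. The real split gave 144 genes and the highest other 0 in Smchd1 KO vs WT, 644 and 0 in Dux KO vs WT, 709 and 0 in Double KO vs Smchd1 KO, and 5619 and 0 in quad KO vs Tet TKO, so that 1 split of the 10, the real one, had as many. In Double KO vs Dux KO the real split gave 2 genes and the highest other 1728, and 4 splits had as many, which points to a structure of the samples.

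Across genes, the log2 change of Smchd1 KO vs WT correlated at -0.15 with Double KO vs Dux KO and 0.0005 with quad KO vs Tet TKO. Of the 105 genes higher in Smchd1 KO, 45 had a positive change in Double KO vs Dux KO (median 0, some with no reads in either). None passed, against 0.00648 expected from the number called. Of the 39 lower, 8 had a negative change (median 0.17). Of the 79 tested in both tables, 13 were higher in quad KO vs Tet TKO, against 13.1 expected. Without the 2-cell-stage list these were 13 of 53, against 8.82 expected. Of the 39 lower, 12 were lower in quad KO, against 8.06 expected. These overlaps were not tested.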
